A study of Mus musculus with 18 samples.

How the data were processed

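Whole-kidney total RNA from 18 mouse kidneys in 6 groups of 3 was sequenced after unilateral ureteral obstruction (UUO, ligation of one ureter, which injures and scars the kidney above it) or without it. The groups were healthy kidney, the contralateral kidney opposite the ligated ureter, wild-type (WT) UUO kidney, and UUO kidneys with a conditional knockout (cKO) of Twist or Snail in endothelial cells (Cdh5-CreERT2, a tamoxifen-inducible Cre) or of Myc in tubular cells (GGT-Cre). Per the labels, the RNA was extracted with TRIzol from a piece of each kidney, and stranded whole-transcriptome libraries were read as 2 reads of 75 bases on a NextSeq500 instrument. Per the labels, the healthy kidneys were all Cre-negative with floxed Twist alleles, and the contralateral and WT UUO groups each held 2 Cre-positive mice without floxed alleles and 1 Cre-negative floxed mouse of the Twist line. The Twist line was a mix of C57BL6, 129sv and Balb/c, and the Snail and Myc lines were a mix of C57BL6 and Balb/c. Replicates are numbered here in the order of the sample records. The labels do not say which kidneys came from the same animal, so p-values measure the spread between these samples.

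The deposited table of raw counts held 31787 gene symbols, of which 958 had no count in any library. Per the submitters' processing notes, bcl2fastq 1.8.4, HTSeq, DESeq2 and the genome build mm10 were used; the aligner, the annotation and the strand setting are not given in the sources used here. The deposited normalized signal was checked against the counts: it was the raw count divided by 1 size factor per library, by the authors, with a largest relative deviation of 5.2142e-15. Each table held 24 columns, of which 18 matched a sample by name; the other 6 columns matched none and entered no step. Total counts ranged from 52.6 to 91.3 M per library. The labels state no sequencing batch or date. Symbols were matched to a reference list of mouse gene names (92.3% matched), and positions came from the GENCODE M21 annotation of the same genome build.

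Raw counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (21050 genes), scaled by the trimmed mean of M-values (TMM), and tested with edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment in 1 robust fit over all 18 libraries with 1 mean per group and 12 residual degrees of freedom. A gene was called changed at an adjusted p under 0.05, two-sided. Unless another test is named, adjusted p-values for genes come from this fit, fold changes are log2 with their standard error (SE), and each group has 3 libraries. Levels are TMM-scaled CPM, counts scaled to the library total, with the standard deviation (SD).

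For 33 gene lists, limma 3.58.1 gave fry, which tests whether the members of a list move on balance one way, and camera, which compares a list with the other genes, both on voom values. Their p-values were adjusted over the 279 tests of lists with at least 3 members. With a preset correlation between genes of 0.01, camera called 132 of the 279; with an estimated correlation it called 0, and the lowest adjusted p was 0.315. No list is therefore described as standing apart from other genes. Members past the threshold were counted over all genes tested and adjusted over the list alone.

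A shift toward the unobstructed level was measured as the median log2 fold change of a knockout against WT UUO over a set of genes. It was signed so that a negative value is toward the contralateral level. The set held genes called by edgeR and changed at least 2-fold for the mean of the other 2 knockouts against contralateral kidneys. Overlaps between knockouts were set beside independent lists and beside 20 simulations of unchanged groups. The simulations also drew the WT UUO libraries anew, shared by all knockout comparisons, with each gene drawn on its own. Where 3 libraries faced 3, the smallest p an exact permutation test can give is 0.10, two-sided.

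The comparisons, the lists and the rule for naming genes were fixed before the data were examined. Per comparison, the rule names Twist1, Snai1 and Myc; the 8 largest rises and falls among called genes with an average log2 CPM of at least 1 and no overlap between groups, without predicted or clone-named genes; up to 4 members of each list with the smallest p; and Vegfa, Hif1a, Cdh5, Pecam1, Acta2, Col1a1 and Havcr1. Alternatives were other size factors, other count filters, DESeq2 1.42.0, limma voom, a 2-fold minimum, Cre presence or sex (Ddx3y against Xist) as a covariate, only the 2 groups compared, and leaving out each library in turn. Chosen after the data were seen were a table without mitochondrially encoded genes, both covariates together, the sex covariate for the shift, leaving out 1 library for the overlap, and leaving out WT UUO replicate 1 with Myc cKO UUO replicate 3.

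The steps were tested on simulated data. In a simulated Twist cKO UUO against WT UUO comparison of 21050 genes, 20% of genes changed 1.5-fold, 62% of those changed 2-fold and 92% of those changed 4-fold were called with the right sign, and 8 unchanged genes were called. In a simulated WT UUO against healthy comparison of 21050 genes, the shares were 20%, 62% and 88%, with 11 unchanged genes called. Both simulations changed few genes, all with an average log2 CPM of at least 1. Genes that may share reads with near-identical copies are named as uncertain. Without a stated strand setting, reads of a gene cannot be told from those of an antisense partner.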

Results

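The 18 libraries measured RNA of whole kidney in 6 groups of 3, for a question about the change of endothelial cells toward a mesenchymal state in the obstructed kidney and its link to oxygen supply and tubular Myc. Total counts (in M) lay between 78.1 and 88.2 in healthy, 86.1 and 91.3 in contralateral and 59.5 and 62.0 in WT UUO kidneys. They lay between 52.6 and 73.9 in Twist cKO UUO, 57.1 and 67.9 in Snail cKO UUO and 56.7 and 72.2 in Myc cKO UUO kidneys. The mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2 took 48.0% ± 2.96 (SD, n = 3) of the counts in healthy and 48.0% ± 1.795 in contralateral kidneys. In the obstructed kidneys they took 19.6% ± 0.675 in WT, 26.7% ± 2.94 in Twist cKO, 25.0% ± 1.20 in Snail cKO and 30.8% ± 4.86 in Myc cKO. On the first principal component, which held 54.3% of the variance, WT UUO kidneys scored 78.38 to 110.3, the knockouts -4.80 to 71.23, and the unobstructed kidneys -134.8 to -99.01. Myc cKO UUO replicate 3 stood apart at -4.80, against 60.28 and 47.27 for replicate 1 and 2. Counts of Ddx3y exceeded those of Xist, as in males, in 1 of 3 libraries of the healthy, contralateral, WT UUO and Twist cKO UUO groups and in 2 of 3 of the Snail and Myc cKO UUO groups.

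The targeted genes came first, as a check of the labels. Twist1, a transcription factor of mesenchymal cells on chromosome 12 (33957671 to 33959829, mm10), had 180, 360 and 93 raw counts in WT UUO and 29, 49 and 21 in Twist cKO UUO kidneys. Its level was 2.59 ± 1.72 CPM (SD, n = 3) in WT UUO, 0.427 ± 0.151 in Twist cKO UUO, 1.56 ± 0.265 in Snail cKO UUO and 1.01 ± 0.186 in Myc cKO UUO. It was 0.191 ± 0.0913 in healthy and 0.230 ± 0.126 in contralateral kidneys. Twist1 fell by 2.59 ± 0.49 (log2, SE; adjusted p = 0.0172) in Twist cKO UUO against WT UUO. Without WT UUO replicate 1 the adjusted p was 0.0701, and without Twist cKO UUO replicate 1, 2 or 3 it was 0.0508, 0.0582 and 0.0525.

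Snai1, which encodes the transcription factor Snail, lies on chromosome 2 (167538195 to 167542814, mm10) and had 271, 276 and 196 raw counts in WT UUO and 165, 126 and 191 in Snail cKO UUO kidneys. Its level was 3.02 ± 0.549 CPM in WT UUO, 1.98 ± 0.293 in Snail cKO UUO, 2.01 ± 0.189 in Twist cKO UUO and 1.32 ± 0.750 in Myc cKO UUO (SD, n = 3). It was 0.435 ± 0.183 in healthy and 0.642 ± 0.0448 in contralateral kidneys. The difference of -0.61 ± 0.38 (log2, SE) between Snail cKO UUO and WT UUO was not past the threshold (adjusted p = 0.487), although the lowest WT UUO library (2.40 CPM) lay above the highest Snail cKO UUO library (2.27 CPM), a separation that, in either direction, 24.9% of all genes tested showed in this comparison and chance gives for 10%. Myc, on chromosome 15 (61985391 to 61990374, mm10), encodes a regulator of growth and metabolism and had 1869, 1907 and 1782 raw counts in WT UUO and 1355, 1613 and 722 in Myc cKO UUO kidneys. Its level was 22.6 ± 1.08 CPM in WT UUO, 16.5 ± 4.95 in Myc cKO UUO, 22.2 ± 6.09 in Twist cKO UUO and 20.7 ± 4.87 in Snail cKO UUO. It was 4.47 ± 0.593 in healthy and 4.10 ± 0.556 in contralateral kidneys. Myc differed by -0.45 ± 0.23 (log2, SE; adjusted p = 0.217) between Myc cKO UUO and WT UUO. Each deletion was directed at 1 cell type by its Cre. The RNA was of whole kidney, so transcripts from all other cells were counted with those of the targeted cells. Where and how completely each gene was deleted was not measured here.

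**Figure D1:**
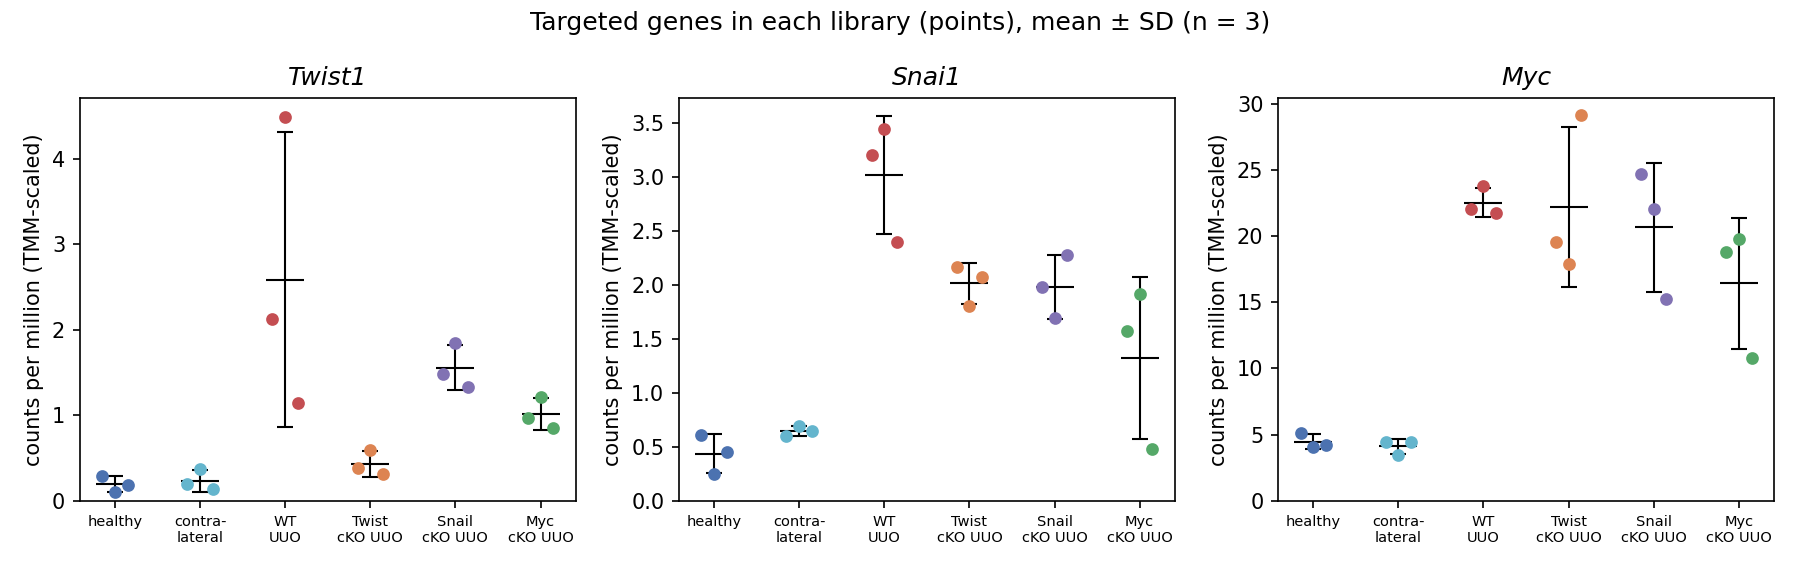
TMM-scaled CPM of Twist1, Snai1 and Myc (vertical axes) in each library (points) of the 6 groups, with the mean and SD of 3 libraries as horizontal and vertical bars. Twist1 averaged 2.59 in WT UUO and 0.427 in Twist cKO UUO kidneys, and Snai1 averaged 3.02 in WT UUO and 1.98 in Snail cKO UUO kidneys.

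WT UUO was set against healthy kidney to show what obstruction changed. The collagen gene Col1a1 rose by 6.11 ± 0.62 (log2, SE, n = 3 per group; adjusted p = 1.36e-06), from 16.4 ± 5.54 to 1138 ± 396 CPM (SD). Lcn2, a marker of injured tubules, rose by 7.94 ± 0.32 (adjusted p = 1.02e-09), and Timp1, an inhibitor of matrix breakdown, by 8.15 ± 0.60. Cubn and Lrp2, which encode receptors for protein uptake in the proximal tubule, changed by -3.11 ± 0.26 and -3.22 ± 0.29, and Acadm, an enzyme of fatty acid oxidation, by -3.27 ± 0.30. The glucose-producing enzyme gene G6pc changed by -6.28 ± 0.90, from 791 ± 171 to 10.2 ± 5.28 CPM. The largest fitted rises were in genes with few or no counts in healthy kidneys, such as Sprr2f with 0 counts in each, so no fold is given for them.

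Of the genes tied to the question of the study, Acta2 (smooth muscle actin) rose by 3.61 ± 0.54 (adjusted p = 5.09e-05), Cdh5 (endothelial cadherin) by 1.47 ± 0.14 (5.03e-07), Pecam1 by 0.73 ± 0.13 (0.00018) and the tubular injury gene Havcr1 by 4.37 ± 1.14 (0.00437) in WT UUO against healthy kidneys. Vegfa, which encodes a growth factor for vessels, changed by -1.27 ± 0.16 (8.9e-06), and Hif1a did not pass the threshold (0.29 ± 0.19, adjusted p = 0.207). Twist1, Snai1 and Myc rose by 3.75 ± 0.53, 2.79 ± 0.41 and 2.34 ± 0.25. The hexokinase gene Hk2 rose by 5.42 ± 0.42 while the later glycolysis gene Pgk1 changed by -1.38 ± 0.20. Tgfb1 rose by 2.50 ± 0.20, the macrophage genes Mrc1 and C1qa by 3.83 ± 0.23 and 3.64 ± 0.24, the chemokine gene Ccl2 by 5.60 ± 0.52 and the mitotic cyclin gene Ccnb1 by 4.72 ± 0.33. The mitochondrially encoded mt-Nd2 changed by -3.70 ± 0.26, and the endothelial receptor gene Kdr by -0.99 ± 0.14. These calls held without any 1 of the 6 libraries.

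Among the gene lists, all 25 extracellular matrix and fibrosis genes rose in WT UUO against healthy kidneys (median log2 3.63; 25 adjusted over the list alone; fry adjusted p = 3.66e-06), as did 16 of 16 macrophage genes (median 3.61). Also higher were 17 of 18 tubular injury genes (median 3.52), 15 of 16 cell cycle genes (3.35), 16 of 17 chemokine and cytokine genes (3.20) and 16 of 17 myofibroblast and pericyte genes (1.93). So were 6 of 6 genes for transcription factors of the mesenchymal transition (1.99) and 7 of 7 urothelial genes (5.20, fry adjusted p = 0.127; 5 genes with a median of 4.101 without WT UUO replicate 1). All 20 fatty acid oxidation genes (median -1.98), 16 citric acid cycle genes (-1.85), 18 nuclear genes of oxidative phosphorylation (-1.87) and 10 mitochondrially encoded genes (-3.45) fell. With them fell 19 of 20 proximal tubule genes (-3.92) and 10 of 11 genes of the loop and distal tubule (-2.52). With an estimated correlation, camera gave adjusted p = 0.315 for the tubular injury list and 0.41 or more for the others. Of 21 endothelial genes 8 rose and 5 fell (median 0.33, fry adjusted p = 0.161). Of 22 hypoxia genes 3 rose and 9 fell (median -0.26, fry adjusted p = 0.138), with a median of -0.544 without WT UUO replicate 1, -0.193 and -0.136 without replicate 2 and 3 and -0.104 without healthy replicate 2. The hypoxia genes that rose numbered 2 without WT UUO replicate 1 or healthy replicate 1 or 3, 5 without WT UUO replicate 2 and 6 without replicate 3. Of 17 glycolysis genes 4 rose and 9 fell (median -0.48, mean 0.07, so the sign differed; fry adjusted p = 0.166). In all, 11856 of 21050 genes changed, 6143 higher and 5713 lower. Of all genes tested 62.5% did not overlap between the groups, where chance gives 10%.

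**Figure D2:**
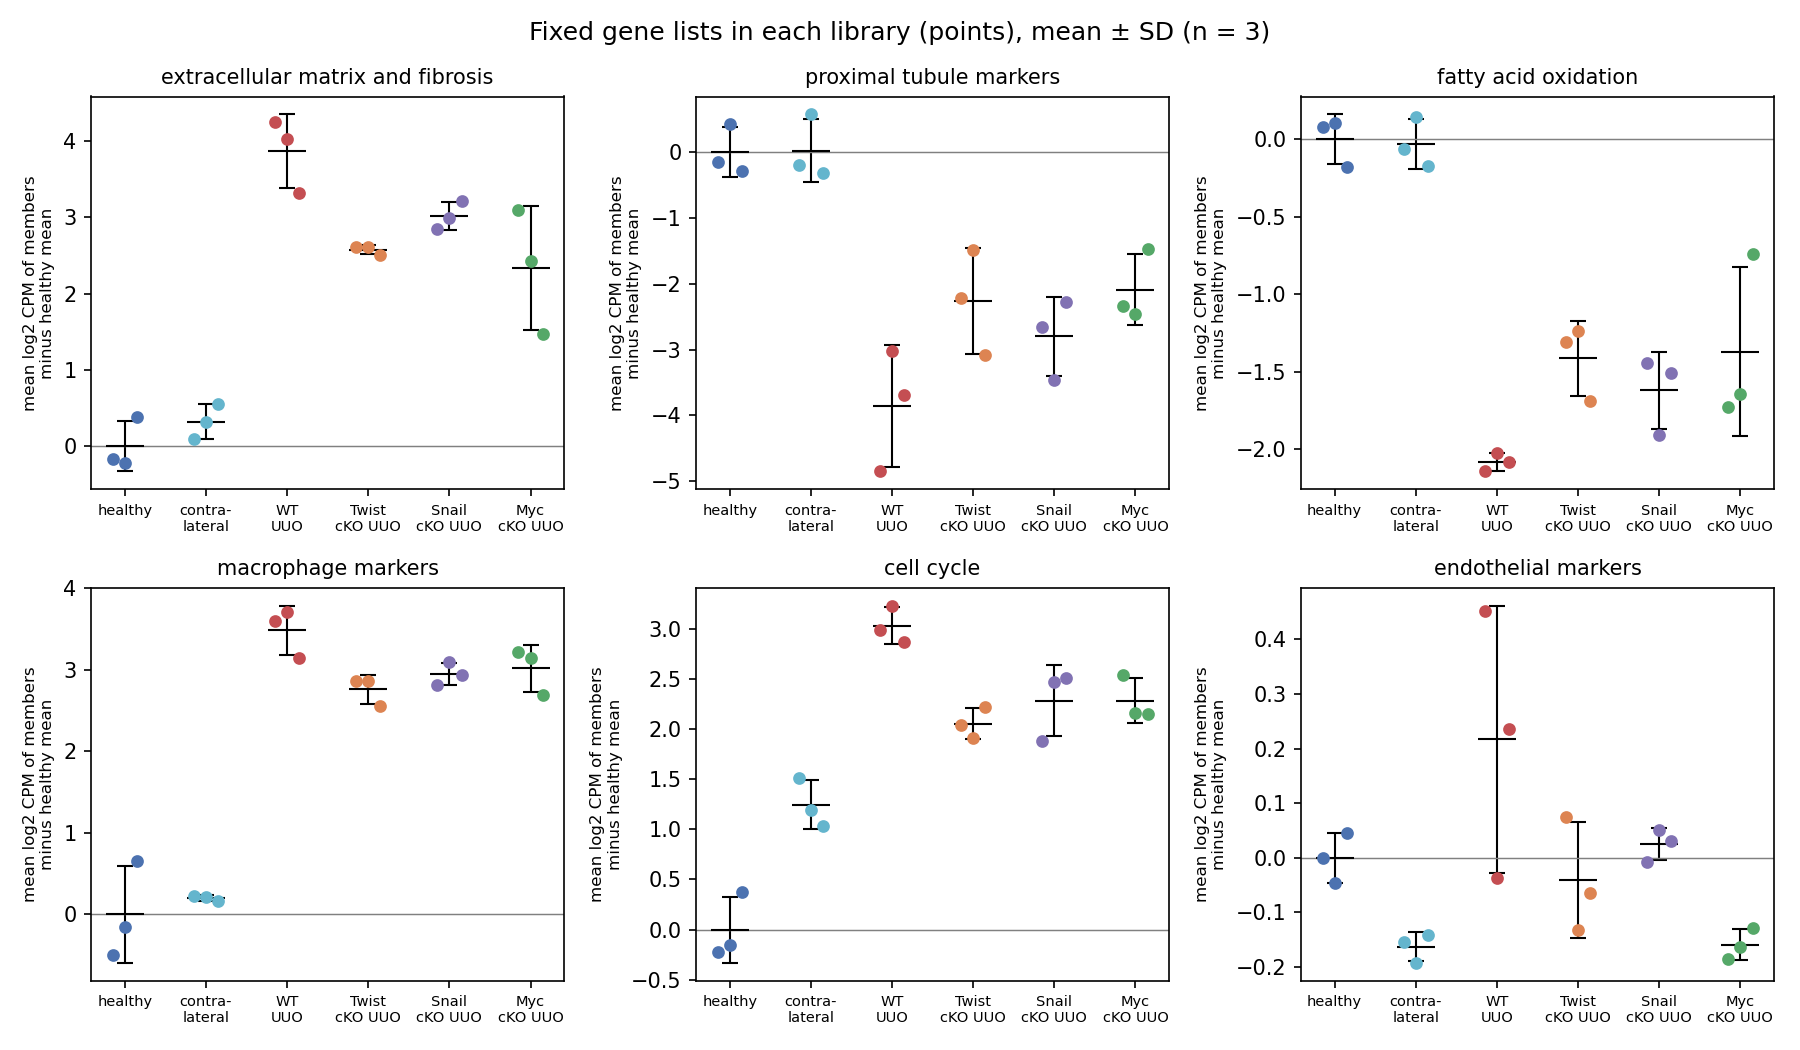
Mean log2 CPM of the members of 6 gene lists in each library (points), minus the mean of the healthy group (vertical axes), with the mean and SD of 3 libraries. In the extracellular matrix panel WT UUO kidneys lie at 3.32 to 4.25, Twist cKO UUO at 2.51 to 2.61, Snail cKO UUO at 2.85 to 3.22 and Myc cKO UUO at 1.48 to 3.10.

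The contralateral kidney was set against the healthy kidney to show what obstruction of one side changed in the other. Genes of cell division were higher in the contralateral kidney: Hmmr rose by 2.50 ± 0.31 (log2, SE, n = 3 per group; adjusted p = 0.0029), the mitotic kinase gene Plk1 by 2.25 ± 0.31 (0.0057) and Ccnb1 by 2.27 ± 0.32, from 0.217 ± 0.0437 to 1.05 ± 0.144 CPM (SD). Of 16 cell cycle genes 9 rose (14 adjusted over the list alone), with a median of 1.36 (fry adjusted p = 0.0161; camera adjusted p = 0.41 with an estimated correlation), with 3 called without healthy replicate 2 and 5 without healthy replicate 1 or contralateral replicate 1. With Cre presence as a covariate 3 were called, and fry gave an adjusted p = 0.246. Of 7 adipocyte genes 1 rose (median 1.69, fry adjusted p = 0.251; 1.124 to 6.345 without 1 library), and the list scored 3.97, 2.29 and 3.81 in contralateral and -1.59, -1.07 and 2.65 in healthy kidneys, as mean log2 CPM relative to the healthy mean. Healthy replicate 3 also scored highest of the healthy kidneys for T cell (0.840) and macrophage markers (0.654). Zfp125, an annotated pseudogene near Twist1, rose by 3.84 ± 0.48 (adjusted p = 0.0029), and Prune2 changed by -2.38 ± 0.36. In the podocyte list 1 of 8 genes rose (5 adjusted over the list alone; median 0.61, fry adjusted p = 0.0167; camera adjusted p = 0.41 with an estimated correlation). With Cre presence as a covariate, fry gave an adjusted p = 0.0344 for the podocyte list, over 31 lists. The fatty acid oxidation, citric acid cycle, oxidative phosphorylation and proximal tubule lists held 0 genes called by edgeR, with medians of -0.021, -0.004, -0.077 and 0.039. Col1a1 (0.86 ± 0.51, adjusted p = 0.412) and Havcr1 (-3.52 ± 1.13, adjusted p = 0.118) did not pass the threshold.

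In total 476 genes changed between contralateral and healthy kidneys, 413 higher and 63 lower, with 3664 at an unadjusted p under 0.05, and 473 of the 476 did not overlap between the groups (20.5% of all genes tested did not, where chance gives 10%). DESeq2 called 1299 and limma voom 240, 3 were called with only the 2 groups in the fit, and 112 changed 2-fold or more. The count was 44 without healthy replicate 2, 200 without healthy replicate 1, 977 without healthy replicate 3, and 136, 162 and 272 without contralateral replicate 1, 2 and 3. The endothelial genes Emcn and Tek fell by 0.67 ± 0.14 (adjusted p = 0.0223) and 0.62 ± 0.15 (0.0487); both lost the threshold without any 1 library other than healthy replicate 3, with adjusted p up to 0.0811 for Emcn without healthy replicate 1 and 0.153 for Tek without contralateral replicate 1. All 3 healthy mice were Cre-negative and 2 of the 3 contralateral mice were Cre-positive, and 75 genes were called with Cre presence as a covariate.

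WT UUO against the contralateral kidney set the obstructed beside the unobstructed side. Col1a1 rose by 5.25 ± 0.60 (log2, SE, n = 3 per group; adjusted p = 4.44e-06), Acta2 by 3.15 ± 0.53, Havcr1 by 7.89 ± 1.35, Lcn2 by 6.96 ± 0.31 and Cdh5 by 1.60 ± 0.14. Twist1, Snai1 and Myc rose by 3.49 ± 0.52, 2.23 ± 0.40 and 2.46 ± 0.25. Vegfa changed by -1.39 ± 0.16 and Slc22a8, an organic anion transporter of the proximal tubule, by -5.59 ± 0.77. These calls held without any 1 of the 6 libraries, and Hif1a did not pass the threshold (adjusted p = 0.262). In total 11281 genes changed, 5799 higher and 5482 lower, and 62.6% of genes tested did not overlap between the groups, where chance gives 10%. The labels do not say which contralateral and obstructed kidneys shared an animal, so no pairing was used. Replicate 1, 2 and 3 of these groups, numbered here in the order of the sample records, agreed in Cre presence, Twist genotype and the sex read from Xist and Ddx3y. The healthy and Twist cKO UUO groups had the same order of sexes, so the match does not show that kidneys shared an animal.

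Twist cKO UUO was set against WT UUO to show what the endothelial loss of Twist changed in the obstructed kidney. Arg1, which encodes an enzyme of macrophages, fell by 3.82 ± 0.73 (log2, SE, n = 3 per group; adjusted p = 0.0185), Fap, a fibroblast gene, by 1.88 ± 0.32 (0.0127), and Acta2 by 2.01 ± 0.51 (0.0378). Cdh5 fell by 0.82 ± 0.13 (adjusted p = 0.0124) and Pecam1 by 0.57 ± 0.13 (0.0275). Of the 21 endothelial genes 4 fell (median -0.31, fry adjusted p = 0.0512; camera adjusted p = 0.497 with an estimated correlation), with 1, 5 and 2 without WT UUO replicate 1, 2 and 3 and 3, 0 and 1 without Twist cKO UUO replicate 1, 2 and 3, and medians from -0.384 to -0.172. Proximal tubule genes were higher: the water channel gene Aqp1 rose by 1.43 ± 0.25 (0.0137), from 69.9 ± 13.8 to 189 ± 19.9 CPM (SD), Slc13a3 by 2.34 ± 0.48 (0.022) and Cubn by 1.24 ± 0.24 (0.0187). Zfp125, which lies within 20 Mb of Twist1, fell by 3.50 ± 0.44 (adjusted p = 0.00532). Zfp125 held in all 6 fits without 1 library. Without WT UUO replicate 1 the adjusted p was 0.0701 for Arg1 and Aqp1, 0.0588 for Fap, 0.153 for Acta2, 0.119 for Pecam1, 0.105 for Slc13a3 and 0.0855 for Cubn. Without Twist cKO UUO replicate 2 it was 0.0519 for Cdh5 and Fap, 0.0589 for Aqp1, 0.0765 for Arg1 and Cubn, 0.0867 for Slc13a3, 0.106 for Pecam1 and 0.11 for Acta2. Arg1 and Acta2 also lost the threshold without Twist cKO UUO replicate 1 (0.0513 and 0.104) and 3 (0.0566 and 0.112), Acta2 without WT UUO replicate 2 (0.107) and Pecam1 without Twist cKO UUO replicate 3 (0.085). Col1a1 (-1.52 ± 0.51, adjusted p = 0.0929), Hif1a (adjusted p = 0.437), Vegfa (0.411) and Havcr1 (0.866) did not pass the threshold.

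Of the extracellular matrix list 15 of 25 genes fell in Twist cKO UUO against WT UUO (25 adjusted over the list alone; median -1.27, fry adjusted p = 0.00626), and of the cell cycle list 11 of 16 (15; -1.08, 0.00111). So did 6 of 17 of the myofibroblast and pericyte list (12; -1.10, 0.00584) and 5 of 16 of the macrophage list (10; -0.86, 0.0144). Of the proximal tubule list 12 of 20 rose (17 adjusted over the list alone; median 1.44, fry adjusted p = 0.00897), and of the loop and distal list 3 of 11 (8; 1.15, 0.0235). Higher too were 4 of 10 of the mitochondrially encoded list (8; 0.94, 0.014) and 4 of 16 of the citric acid cycle list (14; 0.52, 0.0398). For the citric acid cycle list camera gave adjusted p = 0.438 with an estimated correlation, and 0.41 for the other lists named here. In the fatty acid oxidation list 2 of 20 genes rose (12 adjusted over the list alone; median 0.53, fry adjusted p = 0.0555), and the hypoxia list had a median of -0.13, which was 0.105 without WT UUO replicate 1. Of the neutrophil list 1 of 6 genes fell (0 without any 1 library; 5 adjusted over the list alone; median -1.90, fry adjusted p = 0.00901; camera adjusted p = 0.41 with an estimated correlation). The B cell, T cell and chemokine lists held 0 genes called by edgeR, with medians of -1.28, 0.10 and -0.275 (fry adjusted p = 0.0293, 0.891 and 0.441; camera 0.41, 0.953 and 0.807 with an estimated correlation). Adipocyte markers, with 0 of 7 genes called by edgeR and a median of -5.54 (fry adjusted p = 0.435), scored 3.02, 2.30 and -2.14 in the WT UUO and -2.66, -1.48 and -1.98 in the Twist cKO UUO libraries, as mean log2 CPM relative to healthy. Urothelial markers, with 0 of 7 called, had a median of -1.91 (fry adjusted p = 0.393) and -0.334 without WT UUO replicate 1, which scored 6.95 against 4.81 and 3.28 in the other WT UUO libraries. Each list named in this paragraph held 0 genes called by edgeR without WT UUO replicate 1 and 0 without Twist cKO UUO replicate 2. The matrix count was 3 without WT UUO replicate 2, 3 and 2 without Twist cKO UUO replicate 1 and 3, and 16 without WT UUO replicate 3. Cell cycle genes numbered 0 without WT UUO replicate 2 and 1 and 2 without Twist cKO UUO replicate 1 and 3. Macrophage genes numbered 0 without WT UUO replicate 2, and 1 and 0 without Twist cKO UUO replicate 1 and 3, and myofibroblast and pericyte genes 3, 2 and 1. Proximal tubule genes numbered 8 and 6 without WT UUO replicate 2 and 3, and 3 and 9 without Twist cKO UUO replicate 1 and 3. Over the 6 fits without 1 library the median ran from -1.48 to -1.04 for the matrix list and from 1.18 to 2.14 for the proximal tubule list. In total 1111 genes changed, 625 higher and 486 lower, with 4811 at an unadjusted p under 0.05. Of all genes tested 32.6% did not overlap between the groups, where chance gives 10%. The count was 13 without WT UUO replicate 1, 395 without replicate 2 and 1057 without replicate 3, and 316, 24 and 347 without Twist cKO UUO replicate 1, 2 and 3.

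Snail cKO UUO was set against WT UUO for the endothelial loss of Snail. The largest changes were in genes with near-identical copies: Rps3a3, annotated as a processed pseudogene of a ribosomal protein gene, rose by 5.95 ± 0.40 (log2, SE, n = 3 per group; adjusted p = 2.86e-06), from 1.16 ± 0.293 to 71.6 ± 31.2 CPM (SD), while its parent Rps3a1 fell by 1.39 ± 0.21 (0.00945). Hist1h2bm, 1 of a family of histone genes, fell by 2.997 ± 0.31, and the mitochondrially encoded mt-Nd3 rose by 3.85 ± 0.48 (0.00254). Genes of these kinds may share reads with near-identical copies, which was not measured here, so their levels are uncertain. These calls held without any 1 library. Aqp1 rose by 1.42 ± 0.25 (adjusted p = 0.0284) and Fap fell by 1.62 ± 0.31 (0.0426), and Aqp1 lost the threshold without any 1 library except Snail cKO UUO replicate 2, and Fap without any 1 library. Without WT UUO replicate 1 the adjusted p was 0.169 for each, and the highest was 0.18 for Fap without Snail cKO UUO replicate 3. Cdh5 (-0.65 ± 0.13, adjusted p = 0.0559), Acta2 (-1.18, 0.284) and Col1a1 (-1.08 ± 0.50, 0.336) did not pass it.

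Of the cell cycle list 0 of 16 genes were called over all genes tested in Snail cKO UUO against WT UUO, and 14 fell adjusted over the list alone (median -0.84, fry adjusted p = 0.00548; camera adjusted p = 0.41 with an estimated correlation). The matrix list had a median of -0.97, with 1 of 25 genes lower (0 without any 1 library) and 12 adjusted over the list alone (fry adjusted p = 0.056). The macrophage list had a median of -0.63 (fry adjusted p = 0.0485; camera adjusted p = 0.41 with an estimated correlation), and the proximal tubule list a median of 0.93 with 1 of 20 genes higher (0 without any 1 library except Snail cKO UUO replicate 2; fry adjusted p = 0.0885). The endothelial list had 0 of 21 genes called and a median of -0.28 (fry adjusted p = 0.127). Erythrocyte transcripts, with 0 of 5 called (4 lower adjusted over the list alone; median -1.84, fry adjusted p = 0.0796), scored -2.46, -3.05 and -2.96 in the Snail cKO UUO and -1.43, -1.28 and -0.967 in the WT UUO libraries, as mean log2 CPM relative to healthy. Urothelial markers, with 0 of 7 called (median -2.20, fry adjusted p = 0.166; -0.744 without WT UUO replicate 1), scored 0.999, 2.39 and 4.60 against 6.95, 4.81 and 3.28. Adipocyte markers (0 of 7 called, median -0.70, fry adjusted p = 0.729) scored -1.57, -2.35 and 3.18 in Snail cKO UUO replicate 1, 2 and 3. In total edgeR called 63 genes, 34 higher and 29 lower, with 3130 at an unadjusted p under 0.05, where DESeq2 called 773, limma voom 182 and edgeR 145 with sex as a covariate and 11 with only the 2 groups in the fit. The count was 19, 33 and 30 without WT UUO replicate 1, 2 and 3, and 19, 141 and 15 without Snail cKO UUO replicate 1, 2 and 3. The Snail mice were of another strain mix than the WT UUO mice.

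Myc cKO UUO was set against WT UUO for the tubular loss of Myc. Bop1 and Nop2, which serve ribosome assembly and are known Myc targets, fell by 0.77 ± 0.09 (log2, SE, n = 3 per group; adjusted p = 0.00124) and 0.59 ± 0.10 (0.00414), and Cad, for pyrimidine synthesis, by 0.99 ± 0.17 (0.00416). Proximal tubule and mitochondrial genes were higher: Slc6a19, an amino acid transporter, rose by 2.73 ± 0.55 (0.00781), Cubn by 1.37 ± 0.24 (0.00438) and mt-Nd2 by 1.74 ± 0.24 (0.00169). The endothelial genes Cdh5 and Eng were lower, by -0.96 ± 0.13 (0.00177) and -0.52 ± 0.08 (0.00232). The matrix crosslinker gene Loxl1 fell by 1.18 ± 0.17 (0.00177), Fap by 2.03 ± 0.32 (0.00264) and Tgfb1 by 0.89 ± 0.19 (0.00998). These calls held without any 1 of the 6 libraries. G6pc rose by 3.57 ± 0.80 (adjusted p = 0.0122; 0.0623 without WT UUO replicate 1 and 0.0728 without Myc cKO UUO replicate 3), and Col1a1 fell by 1.90 ± 0.51 (adjusted p = 0.0286). For Col1a1 the adjusted p was 0.106 and 0.0774 without WT UUO replicate 1 and 2, and 0.0899 and 0.0887 without Myc cKO UUO replicate 2 and 3. Acta2 (-1.31, adjusted p = 0.0995), Hif1a (0.346) and Vegfa (0.474) did not pass the threshold. Trim12a fell to 3, 2 and 0 raw counts from 886, 753 and 1542 in WT UUO; it and its neighbours Trim5 and Gvin1 have close copies, so their levels are uncertain.

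Of the matrix list 21 of 25 genes fell in Myc cKO UUO against WT UUO (23 adjusted over the list alone; median -1.40, fry adjusted p = 0.00169). Of 28 Myc targets 13 fell and 1 rose (16 and 1; -0.30, 0.00348), and of 21 endothelial genes 9 fell (10 lower and 1 higher; -0.42, 0.00614). Of the proximal tubule list 13 of 20 genes rose (17 adjusted over the list alone; median 1.64, fry adjusted p = 0.00654), and of the mitochondrially encoded list 8 of 10 (10; 1.36, 0.00115). With an estimated correlation, camera gave adjusted p = 0.41 for each of these lists. In the fatty acid oxidation list 11 of 20 genes rose (13 adjusted over the list alone; median 0.73, fry adjusted p = 0.0456; camera 0.461 with an estimated correlation). So did, in the citric acid cycle list 11 of 16 (15; 0.60, 0.024; 0.438) and in the oxidative phosphorylation list 11 of 18 (16; 0.57, 0.0431; 0.497). The glycolysis list had a median of -0.23 and 3 of 17 genes lower (fry adjusted p = 0.785; median -0.058 with 0 lower without WT UUO replicate 1, and -0.389 with 2 lower without Myc cKO UUO replicate 3), and the hypoxia list a median of -0.07, which was 0.224 without WT UUO replicate 1 and 0.014 without Myc cKO UUO replicate 2. Urothelial markers, with 0 of 7 called (3 lower adjusted over the list alone; median -2.61, fry adjusted p = 0.122), scored 6.95, 4.81 and 3.28 in the WT UUO and 4.25, 2.31 and -0.747 in the Myc cKO UUO libraries. Their median was -1.079 without WT UUO replicate 1 and -4.038, with 4 lower, without Myc cKO UUO replicate 1. Erythrocyte transcripts scored -2.92, -1.95 and -0.153 in Myc cKO UUO replicate 1, 2 and 3. Adipocyte markers scored 2.17, -2.57 and 2.39 in the Myc cKO UUO and 3.02, 2.30 and -2.14 in the WT UUO libraries. Their median ran from -0.876 to 0.77 without 1 library, with 0 called. Leaving out WT UUO replicate 1, 12 matrix genes, 7 Myc targets and 2 endothelial genes fell, and 5 proximal tubule, 0 fatty acid oxidation, 2 citric acid cycle and 0 oxidative phosphorylation genes rose. Leaving out Myc cKO UUO replicate 3, 13 matrix genes, 7 Myc targets and 5 endothelial genes fell, and 4 proximal tubule, 0 fatty acid oxidation, 2 citric acid cycle and 0 oxidative phosphorylation genes rose. Myc targets that fell numbered 6 and 8 without WT UUO replicate 2 and 3 and 6 without Myc cKO UUO replicate 2. Without 1 library the median of this list ran from -0.343 to -0.208 for Myc cKO UUO against WT UUO. It ran from -0.211 to -0.138 for Twist, with 0 to 2 genes lower, and from -0.178 to -0.065 for Snail, with 0 lower. The median was thus below 0 in the other knockouts too. Fatty acid oxidation, citric acid cycle and oxidative phosphorylation genes that rose numbered 6, 6 and 5 without WT UUO replicate 2 and 4, 7 and 6 without replicate 3. The endothelial count was 6 without WT UUO replicate 3 and 5 without Myc cKO UUO replicate 2, and the mitochondrially encoded count was 7 or more in each fit. In total 2572 genes changed, 1117 higher and 1455 lower, with 5867 at an unadjusted p under 0.05. Of all genes tested 31.8% did not overlap between the groups, where chance gives 10%. The count was 797, 1553 and 1849 without WT UUO replicate 1, 2 and 3, and 3025, 1761 and 974 without Myc cKO UUO replicate 1, 2 and 3. It was 5 with only the 2 groups in the fit.

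**Figure D3:**
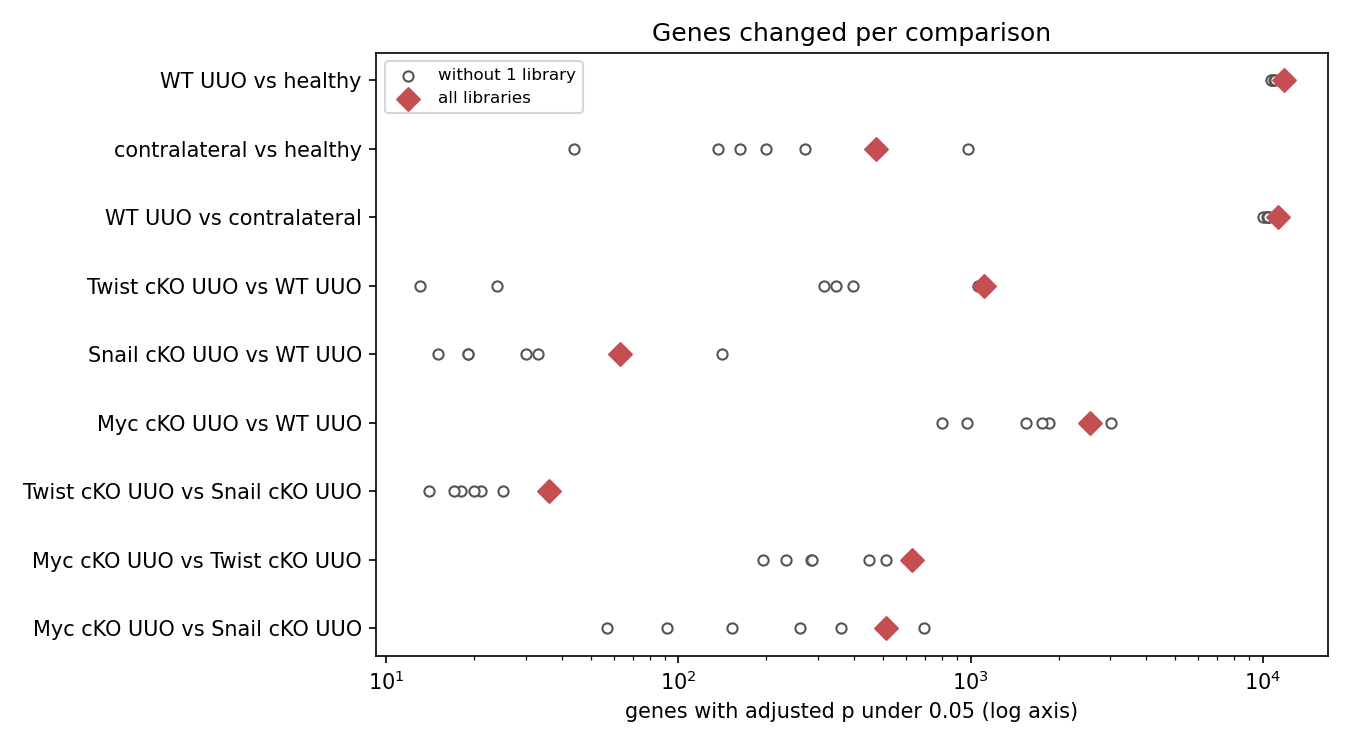
Number of genes with an adjusted p under 0.05 in each of the 9 comparisons (log axis), with all libraries (diamonds) and without 1 library of the groups compared (circles). Twist cKO UUO against WT UUO gave 1111 genes with all libraries and 13 to 1057 without 1.

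Direct tests between the knockouts asked which genes differed between them. Between Twist and Snail cKO UUO, Iah1, within 20 Mb of Twist1 like Zfp125 and Greb1, was higher in Twist cKO UUO by 1.31 ± 0.19 (log2, SE, n = 3 per group; adjusted p = 0.00695), and Fggy, a sugar kinase gene, by 1.09 ± 0.15 (0.00459). Zfp125 was lower in Twist cKO UUO by -3.53 ± 0.44 (0.00187) and Rps3a3, whose reads are uncertain, by -6.00 ± 0.40. These calls held without any 1 library. Greb1 was higher by 2.53 ± 0.45 (adjusted p = 0.04), with 0.139, 0.121 and 0.0989 without Twist cKO UUO replicate 1, 2 and 3 and 0.206, 0.127 and 0.191 without Snail cKO UUO replicate 1, 2 and 3. In total edgeR called 36 genes, 18 higher and 18 lower, with 1373 at an unadjusted p under 0.05, where DESeq2 called 152 and edgeR 56 with only the 2 groups in the fit. The count was 14, 21 and 20 without Twist cKO UUO replicate 1, 2 and 3, and 18, 25 and 17 without Snail cKO UUO replicate 1, 2 and 3. No list held a gene called over all genes tested; 5 of 5 erythrocyte genes were higher adjusted over the list alone (median 1.77, fry adjusted p = 0.0885).

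Between Myc and Twist cKO UUO, the endothelial receptor gene Eng was lower in Myc cKO UUO by -0.62 ± 0.08 (log2, SE, n = 3 per group; adjusted p = 0.00167), Bop1 by -0.55 ± 0.09 (0.00689) and Ski, a brake on TGF-beta signalling, by -0.60 ± 0.10 (0.00632). Zfp125 was higher by 3.60 ± 0.44 (0.00167) and Acp1, near Twist1, by 1.34 ± 0.22 (0.00614). These calls held without any 1 library. Of 17 TGF-beta pathway genes 3 were lower (4 adjusted over the list alone; median -0.44, fry adjusted p = 0.0429; camera adjusted p = 0.41 with an estimated correlation), and of 28 Myc targets 4 were lower (median 0.05, mean -0.07, so the sign differed). The TGF-beta median was -0.104 and -0.137 without Myc cKO UUO replicate 3 and 2, -0.204 without Twist cKO UUO replicate 1 and -0.631 without Myc cKO UUO replicate 1, and the count was 1 without Twist cKO UUO replicate 2 or 3, and the Myc target count was 1 in 4 of the 6 fits, with 2 without Twist cKO UUO replicate 1 and 4 without Myc cKO UUO replicate 1. In total 630 genes differed, 93 higher and 537 lower in Myc cKO UUO, with 285, 234 and 194 without Twist cKO UUO replicate 1, 2 and 3, and 450, 286 and 515 without Myc cKO UUO replicate 1, 2 and 3. Only 2 groups in the fit gave 15, of which 9 were higher and 6 lower, and a 2-fold minimum left 31 higher and 31 lower. DESeq2 called 1582, 413 higher and 1169 lower. Adipocyte markers scored 2.17, -2.57 and 2.39 in the Myc cKO UUO and -2.66, -1.48 and -1.98 in the Twist cKO UUO libraries, as mean log2 CPM relative to healthy. Their median ran from 5.14 to 5.93 without 1 library, with 0 called. The Twist and Myc mice were of different strain mixes.

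Between Myc and Snail cKO UUO, Trim30d, an interferon-induced gene, was lower in Myc cKO UUO by -3.09 ± 0.47 (log2, SE, n = 3 per group; adjusted p = 0.00696) in all 6 fits without 1 library. Trim30d is a Trim gene like Trim12a and Trim5. Reads shared with close copies were not measured, so its level is uncertain. Eng was lower by -0.47 ± 0.08 (0.00991), Bop1 by -0.54 ± 0.09 (0.0102) and Notch3, a receptor gene of pericytes, by -0.65 ± 0.11 (0.0096). Without Snail cKO UUO replicate 1 the adjusted p was 0.0677 for Eng and 0.0646 for Bop1, and without Snail cKO UUO replicate 3 it was 0.0519 for Notch3. Of 10 mitochondrially encoded genes 3 were higher in Myc cKO UUO (7 adjusted over the list alone; median 0.87, fry adjusted p = 0.0467; camera adjusted p = 0.41 with an estimated correlation). edgeR called 7 of them without Myc cKO UUO replicate 1 and 0 without any 1 of the other 5 libraries. Without 1 library, erythrocyte transcripts had medians from 0.543 to 2.44 with 0 to 3 genes called higher. Adipocyte markers had medians from -0.023 to 4.74 with 0 called. In total 515 genes differed, 110 higher and 405 lower, with 57, 361 and 91 without Snail cKO UUO replicate 1, 2 and 3, and 691, 153 and 261 without Myc cKO UUO replicate 1, 2 and 3. A fit of only the 2 groups gave 16, with 5 higher and 11 lower, a 2-fold minimum left 57 higher and 48 lower, and DESeq2 called 1393, with 450 higher and 943 lower.

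Genes raised or lowered in the mean of the other knockouts against contralateral kidneys were then followed as 1 set in each knockout. In Twist cKO UUO, 3025 raised and 2015 lowered genes had medians of -0.44 and 0.64 against WT UUO. Of these genes 84.4% lay toward the contralateral level, with a signed median of -0.52. Limma's fry gave an adjusted p = 0.00564 for the raised and 0.00278 for the lowered genes, over 6 tests. In Myc cKO UUO the medians were -0.46 and 0.65, 83.6% lay toward that level and the signed median was -0.54 (fry adjusted p = 0.00278 for both parts). In Snail cKO UUO the medians were -0.29 and 0.41, 77.5% lay toward it and the signed median was -0.33 (fry adjusted p = 0.033 and 0.0235). The same genes had moved by a median of 2.23 and -2.03 in WT UUO against contralateral for the Twist set. Without 1 library the signed median ran from -0.57 to -0.47 for Twist and from -0.66 to -0.36 for Myc, with an unadjusted fry p under the threshold for both parts in each fit. For Snail it ran from -0.41 to -0.28, and the unadjusted fry p of the raised genes was 0.0923 and 0.0833 without WT UUO replicate 1 and 2 and 0.103 and 0.106 without Snail cKO UUO replicate 1 and 3. That of the lowered genes was 0.0798 without WT UUO replicate 1 and 0.0641 without Snail cKO UUO replicate 3. Camera with an estimated correlation gave 0.0253 and 0.00816 for Twist, 0.0342 and 0.0157 for Myc, and 0.0738 and 0.045 for Snail, unadjusted. An exact permutation test of the mean score per library gave p = 0.10 for each knockout, the smallest value that 3 libraries against 3 allow.

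The knockout effects were compared with each other, all against the same 3 WT UUO libraries. Twist and Myc cKO UUO shared 339 genes that were higher and 263 that were lower, with 3 in opposite directions, where independent lists would share 33.2 and 33.6. Twist and Snail cKO UUO shared 20 and 14, with 1 opposite (independent lists 1.01 and 0.67), and Snail and Myc cKO UUO shared 22 and 17, with 2 opposite (1.804 and 2.005). Over 21050 genes, which are not independent replicates, Pearson's r between the fold changes was 0.660 for Twist and Myc, 0.596 for Twist and Snail and 0.578 for Snail and Myc. Unchanged groups simulated against shared controls, which were simulated too, gave a mean of 0.492, 0.494 and 0.493. Genes were drawn independently there, so a control library shifted as a whole was not simulated. The covariances were 0.377, 0.296 and 0.285 against simulated 0.125, 0.127 and 0.126, so the differences were 0.252, 0.169 and 0.160. Part of the excess may come from the shared controls, which 3 libraries do not allow to be split. The shared genes numbered 5 for Twist and Myc, 1 for Twist and Snail and 4 for Snail and Myc without WT UUO replicate 1. For Twist and Myc they numbered 261 without WT UUO replicate 2, 168, 14 and 240 without Twist cKO UUO replicate 1, 2 and 3, and 391, 400 and 867 without Myc cKO UUO replicate 2, 3 and 1. For Twist and Snail they numbered 16 and 13 without WT UUO replicate 2 and 3, 10, 4 and 14 without Twist cKO UUO replicate 1, 2 and 3, and 4, 92 and 1 without Snail cKO UUO replicate 1, 2 and 3. For Snail and Myc they numbered 16 and 15 without WT UUO replicate 2 and 3, 5, 77 and 3 without Snail cKO UUO replicate 1, 2 and 3, and 25 and 102 without Myc cKO UUO replicate 2 and 3.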

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

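All tests of explanations in this part were chosen after the results were seen; the counts over other splits of the libraries were planned.

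The knockouts differed from each other by a direct test: 36 genes between Twist and Snail cKO UUO, 630 between Myc and Twist cKO UUO and 515 between Myc and Snail cKO UUO. Each pair of groups of 3 has 10 splits, too few for a share under 0.05. The highest count of any other split was 2 in each of the first and second of these pairs and 1 in the last. Against WT UUO, the Twist, Snail and Myc cKO UUO counts were 1111, 63 and 2572, and the highest of the other splits gave 0, 0 and 2. For obstruction, WT UUO against healthy and against contralateral kidneys gave 11856 and 11281 with 1 and 1 as the highest of the others, and contralateral against healthy gave 476 with 5. In each of the 9 comparisons 1 of the 10 splits, the real one, gave a count as large. Every other split mixes the groups compared, which puts a real difference into the spread, so its count is no rate of false calls.

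Of the genes called between Twist and Snail cKO UUO, many lay near the targeted genes: 11 of the 32 with a position were within 20 Mb of Twist1 or Snai1, which was 34.4% against 2.996% of all genes tested (one-sided Fisher exact p = 1.16e-09). Strain segments that travel with the floxed alleles may account for this, since the mice came from mixed strains. All Twist and Snail cKO UUO mice were positive for the same Cdh5-CreERT2, so Cre presence alone does not separate these groups. Against the loss of Twist1 as the whole cause, 4 of the 8 called genes near Twist1 (Greb1, 3110053B16Rik, Gm10478 and Gm4419), 50%, separated kidneys without the knockout. They already separated 5 Cre-negative floxed from 4 Cre-positive unfloxed kidneys, as did 0.713% of genes elsewhere. With overlapping genes counted as 1 locus, 3 of 6 loci did so (one-sided Fisher exact p = 7.44e-06). All 8 genes lie between 15606412 and 21421064 on chromosome 12 and can be inherited together. Both Fisher tests take genes or loci as independent, so their p-values overstate the evidence. The 8 genes had been chosen as called and the genes elsewhere had not, so 50% and 0.713% are shares of unlike sets. The 5 floxed kidneys also included all 3 healthy ones and the 4 unfloxed ones did not, so the split partly followed the groups. The comparison with genes elsewhere replaced a bound of 50%, also set after the result was seen. Under that bound the same share had not counted against Cre activity or the loss of Twist1. The other 4 (Zfp125, Iah1, Gm4804 and 5730507C01Rik) were shifted the same way in the mean without separating. The exact sign test gave p = 0.0625, the smallest value 4 genes allow, so it could not have passed the threshold. It also counted Zfp125 apart, although Zfp125 overlaps 3110053B16Rik and Gm10478, which did separate. For these 4 genes strain segments and the loss of Twist1 both stay open. Zfp125 had 0.0610 to 0.328 CPM in the 3 healthy kidneys and 0.190 to 0.329 in Twist cKO UUO, but 1.79 and 2.36 in the other 2 Cre-negative floxed kidneys. A lower level of Twist1 from the floxed allele without Cre was not tested, and neither were the genes near Snai1.

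The Twist and Myc cKO UUO kidneys lay nearer the unobstructed level than WT UUO kidneys. An atypical library was not the whole cause, since the signed median stayed at -0.469 or below for Twist and at -0.362 or below for Myc without any 1 library. A larger share of cortex in the piece sampled would raise podocyte genes with proximal tubule genes, but the podocyte median was -0.015 for Twist and -0.08 for Myc. The upper bounds of the podocyte means, 0.145 and 0.230, lay under 0.718 and 0.822, levels set from the proximal tubule medians seen. These bounds use the standard error over the 8 podocyte genes of the same libraries, not the spread between kidneys. They do not measure how the pieces sampled differed, so a larger share of cortex is not excluded. For Myc, the strain background cannot be told apart from the knockout, because 0 obstructed control libraries came from the Myc line, and for both knockouts a milder obstruction, fat or urothelium in the pieces sampled and an effect of the knockout stay open as untested.

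Cell cycle genes were higher in contralateral than in healthy kidneys, which also differed in Cre presence and Twist genotype. With Cre presence as a covariate the median of the list was 0.932 against 1.36 without it, 3 genes were called instead of 9, and limma's fry gave an adjusted p = 0.246 over 31 lists. The call was lost and most of the shift was not, and because Cre presence is tied to the group, with 0 Cre-positive healthy libraries, genotype cannot be told apart from the effect of the surgery. The 1 contralateral library of the healthy genotype, replicate 3, scored 1.04 for the list against -0.224, -0.154 and 0.379 in healthy kidneys, but a single library excludes nothing. The lowest median without 1 library was 1.05, so 1 atypical library was not the whole cause of the shift. A response of the remaining kidney and fat in the pieces sampled stay open as untested.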

How the results depend on the processing

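The sex and Cre covariates together, leaving out WT UUO replicate 1 with Myc cKO UUO replicate 3, the table without mitochondrially encoded genes, the sex covariate for the shift and leaving out 1 library for the overlap were chosen after seeing the data. No paired analysis was made, because the labels do not say which kidneys shared an animal.

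With other size factors, with the authors' size factors, with at least 1 CPM in 3 libraries and without mitochondrially encoded genes, each of the 9 counts stayed within 1.5 times its value. A 2-fold minimum, which can only remove genes, left 6825 of 11856 for WT UUO against healthy, 112 for contralateral against healthy, 6430 for WT UUO against contralateral, 475 for Twist and 783 for Myc cKO UUO against WT UUO, 62 for Myc against Twist and 105 for Myc against Snail. With 2-fold genes only, the knockouts shared 16 (Twist and Snail), 261 (Twist and Myc) and 21 (Snail and Myc).

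DESeq2 called 1299 genes for contralateral against healthy, 2421 for Twist and 773 for Snail against WT UUO, 152 for Twist against Snail, 1582 for Myc against Twist and 1393 for Myc against Snail. Limma voom called 240 for contralateral against healthy and 182 for Snail against WT UUO. No filter gave 733 for Twist against WT UUO. With only the 2 groups in the fit, which leaves fewer samples for the spread, the counts were 3 for contralateral against healthy, 11 for Snail and 5 for Myc against WT UUO, 56 for Twist against Snail, 15 for Myc against Twist and 16 for Myc against Snail. The sex covariate gave 718 for contralateral against healthy, 1831 for Twist and 145 for Snail against WT UUO. The Cre covariate gave 75 for contralateral against healthy, and both covariates 41 there, 1908 for Twist and 223 for Snail. Without WT UUO replicate 1 and Myc cKO UUO replicate 3, Myc against WT UUO gave 287. The loss of samples was the same for Twist against WT UUO, which gave 1234 genes with only the 2 groups in the fit and 1111 in the main fit. Twist against Snail rose from 36. Fewer samples thus did not lower every count. Their cost can differ with the spread of the groups compared, so they stay open as a cause of the lower counts. The cause of these changes was not tested.

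Without 1 library the counts ran from 44 to 977 for contralateral against healthy, 13 to 1057 for Twist, 15 to 141 for Snail and 797 to 3025 for Myc against WT UUO, 14 to 25 for Twist against Snail, 194 to 515 for Myc against Twist and 57 to 691 for Myc against Snail. The 2 obstruction comparisons stayed between 10643 and 11596 and between 9987 and 10518. The shared genes ran from 1 to 92 for Twist and Snail, 5 to 867 for Twist and Myc and 3 to 102 for Snail and Myc.

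The shift toward the unobstructed level kept its sign under each alternative, and for Twist and Myc also its side of the threshold. For Snail the signed median was -0.282 with the sex covariate, no longer past the threshold for the raised genes, and -0.411 to -0.280 without 1 library. Without WT UUO replicate 1 or Snail cKO UUO replicate 3 neither the raised nor the lowered genes passed, and without WT UUO replicate 2 or Snail cKO UUO replicate 1 the raised genes did not. Camera called 132 list tests with the preset and 0 with an estimated correlation, whose own construction allows for members that vary together. Counted over each named gene in each fit without 1 library, 7160 cases kept the call or the lack of one. In 803 cases the call was lost, in 59 one was gained, and 0 reversed. Under the other alternatives the numbers were 13953, 502, 223 and 0. In the simulated Twist comparison, which changed few genes, 20% of genes changed 1.5-fold were called with 3 libraries per group. The adjusted threshold depends on how many genes change, so this share does not carry over to every comparison. Of the 2572 genes called for Myc cKO UUO against WT UUO, 783 changed 2-fold or more and the others less.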

Other observations

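The values in this part were singled out after they were seen, the tests of nearness were chosen after the results were seen, and no explanation was tested here. Trim12a had 214, 1 and 1 raw counts in the 3 healthy kidneys, 3, 2 and 0 in Myc cKO UUO and from 253 to 1542 in the contralateral and WT UUO kidneys. Its neighbour Trim5 on chromosome 7 had 39, 4 and 8 raw counts in healthy and 6, 6 and 7 in Myc cKO UUO kidneys. Low Trim12a counts were thus found in 2 kidneys of the Twist line as well as in the Myc line.

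Near the targeted genes, 16 of 1056 genes called for Twist cKO UUO against WT UUO were within 20 Mb of Twist1 (1.52% against 0.698% of genes tested; adjusted one-sided Fisher exact p = 0.0147 over 18 tests). For Snail cKO UUO against WT UUO, 6 of 60 were near Snai1 (10% against 2.30%, adjusted p = 0.0147), and for Myc cKO UUO 40 of 2444 were near Myc (1.64% against 1.54%, adjusted p = 0.642). Between Twist and Snail cKO UUO, 8 of 32 were near Twist1 (adjusted p = 7.53e-10) and 3 near Snai1 (adjusted p = 0.132). These tests take genes as independent, although neighbours can be inherited together.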
